A study of Mus musculus with 16 samples.

How the data were processed

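Total RNA of B220-positive splenic B cells from 3'RR-deficient and wild-type mice was measured on 16 single-colour (Cy3) Agilent mouse arrays. The labels give 0.2 microgram of RNA and a RIN number of 9 for every sample, and name a low-input amplification and labelling kit. Per the labels, the deficient mice carry the knocked-out 129 IgH allele in a BALBC background and have the strain entry BALBC, while the wild-type mice have the strain entry 129. Genotype and strain entry therefore go together in every sample, and no comparison made here tells them apart. The labels place the arrays on 2 slides with 4 arrays of each genotype on each slide, and the genotypes exchange the upper and lower positions between slides. Each slide was scanned on 1 day. The series text speaks of 4 mice per genotype, while 8 arrays per genotype were analysed. The labels number the samples within each slide, with deficient numbers 9 to 12 on slide 1 and 1 to 4 on slide 2. Wild-type numbers 2 and 5 occur on both slides, but Ddx3y was well above background under these numbers on slide 2 and not on slide 1, so they are not the same mice. No label says that each array is a mouse of its own, so p-values measure the spread between these samples, which may be partly technical.

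The spot intensity of each array is the authors' scanner output, and per the file headers it was extracted with Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed intensity was background-subtracted and detrended within each array, with surrogate values for dim spots, and it was not normalized between arrays. Coordinates follow mm9, per the file headers. The series also holds a table of log2 values as the authors deposited it, with 16 columns that each ranked best with the mean signal of their own array. Its column medians lay between 5.58 and 5.61 on slide 1 and between 6.49 and 6.50 on slide 2, so the slides had been scaled separately. The submitters' processing notes name limma for the slide 2 samples, with no version or role. The background handling behind that table and its exact steps are not given in the sources used here. It served as an alternative within slides, and it was not used to compare the slides.

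Each array held 62976 spots, of which 3671 were controls and were left out after scaling. The other spots stood for 55681 probes with 34821 gene names. Accessions of 27509 probes matched the RefSeq gene table of assembly GRCm38.p6, used for symbols alone, and 2017 of them had another current symbol there. Every gene is given by its name in the files, which can be old. The probe of Mnda has the current symbol Ifi211 and that of Etohi1 Zfp971. The log2 processed signal minus the array's 75th percentile was analysed. Spots of 1 probe were averaged, and a probe was kept if well above background on at least 4 of 16 arrays. The brightest probe stood for a gene, which left 22677 genes. The 75th percentile of signal ran from 576 to 851 on slide 1 and from 596 to 990 on slide 2. Between 26065 and 29250 probes were well above background on slide 1 arrays, and between 29961 and 34193 on slide 2 arrays. The number of arrays limits the precision.

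One limma model (limma 3.58.1, R 4.3.3) with a mean for each of the 4 groups of genotype and slide gave the difference over both slides, within each slide, between the slides' differences, and between the slides. Every p printed for a gene, a probe or a gene list is limma's, adjusted by Benjamini-Hochberg, with a threshold of 0.05. Differences are deficient minus wild type on the log2 scale, with the standard error (SE) of the fit and 4 arrays per group. A probe not well above background on any array of a group has only a bound there. Its fold is then given as at least the bright group's mean over the higher of the dim probe's signal and the lowest signal well above background on each array, with no fold where that is under 1 or both groups were dim. Medians are over fitted differences, and where dim members at their bound change a list's median at the precision printed, that value is given as well. It leaves out members dim in both genotypes of a slide (for the comparison of slides, in every group).

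Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 3 measured members. Camera with an estimated correlation and fry were alternatives. The list of heavy chain constant genes matched only 1 measured name and the list of light chain and surrogate light chain genes only 2, so neither was tested as a list. Heavy chain probes were instead taken by position between named landmarks and each probe was tested on its own, a choice made after seeing the data. The gene lists, the tests, the other alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 12 higher and 12 lower genes with the largest difference over both slides among those past the threshold, with 1 sign on both slides and an official symbol. It also takes every measured member of the heavy chain constant list, the 5 largest per direction for each slide and for the difference between slides, and up to 4 members of each other list with the smallest p. After the data were seen this was narrowed to 4 members of a list past the threshold and 2 of any other. Genes and probes outside the rule were chosen after their values were seen. Not every gene the rule takes is reported here.

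The alternatives were normexp background correction with an offset of 50, quantile and median scaling, the authors' value table, other filters on dim probes, the mean over probes, array weights, other slide terms, each slide fitted alone, a replicate block on slide 2 and leaving out each array in turn. A fold threshold of 2 was also applied. A term for Y-linked signal, leaving out genes on chromosomes X and Y, scaling by the positive control transcripts, and setting every dim array to its floor, the higher of its lowest signal well above background and the probe's own, were added after seeing the data. The procedure was tested on simulated data with 200 changed genes among 22677. Over both slides it recovered 55.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97% of those changed 4-fold, with 167 calls of which 11 were false. For slide 1 the shares were 44.8%, 61.2% and 89.4%, and for slide 2 they were 38.8%, 61.2% and 87.9%. None of these genes differed between slides and 0 were called for that comparison. In a further simulation with 200 genes changed on slide 2 alone, added after seeing the data, the shares for the difference between slides were 11.9%, 40.3% and 77.3%, with 90 calls of which 4 were false. In the simulated lists the shifted list passed and 0 of the others did. Noise was drawn independently for each gene there, while the estimated correlation within the real lists reached 0.76. The simulation therefore does not test lists whose members move together. Tables were handled with the R package data.table, version 1.17.8, and with pandas 2.3.3 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.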

Results

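The series compared the transcriptome of splenic B cells of mice that lack the 3' regulatory region (3'RR) of the immunoglobulin heavy chain locus with that of wild-type mice. The 3'RR is a cluster of enhancers downstream of the last constant gene of the locus, known to drive heavy chain transcription and class switch recombination. Cells were purified with beads against B220, a surface marker of B cells. There were 4 deficient and 4 wild-type arrays on each of 2 slides. Signals of arrays within a group correlated across genes with Pearson's r between 0.981 and 0.997, against 0.971 to 0.987 between genotypes on 1 slide and 0.89 to 0.916 between slides, where genes are not independent replicates. The largest component of variation separated the slides and held 73.9% of the variance, and the next, with 7.18%, separated the genotypes on both slides. Genotype and strain entry go together in the labels, so each difference given is between these mice and not between genotypes alone. Ddx3y, a Y-linked gene, was well above background on 2 of 4 arrays of each genotype on slide 1, and on slide 2 on 2 of 4 deficient and 4 of 4 wild-type arrays.

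Constant region transcripts of the heavy chain locus were far lower in deficient cells. Of the 13 measured probes on chromosome 12 between Tmem121, the gene that flanks the locus on the 3'RR side, and the delta constant gene (mm9, 114427734 to 114654276), 12 fell and none rose, with a median log2 difference of -4.40, and -4.36 with dim probes at their bound. These probes cover the gamma and epsilon constant genes, which encode the heavy chains of switched antibody classes. Heavy chain variable segments, which encode the antigen-binding part, fell as well, with 90 of 101 measured probes lower and a median of -2.04, and -2.0 with dim probes at their bound. Constant probes of the kappa and lambda light chains, which lie on other chromosomes, gave a median of -0.21 with 0 of 3 past the threshold of limma's test. At an unadjusted p under 0.05 2 were lower.

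Among single probes over both slides, the gamma 3 probe fell by 5.42 (SE 0.15, adjusted p 2.18e-11), the probe for IgG2a by 5.38 (SE 0.31, adjusted p 4.78e-08) and the gamma 2C probe by 4.31 (SE 0.40, adjusted p 5.57e-06; well above background on 1 of 4 deficient arrays of slide 2). The epsilon probe (adjusted p 8.31e-09) was not well above background in the deficient arrays of slide 1 and was at least 11.3-fold lower there, and 21-fold lower on slide 2. The pair of gamma 1 probes fell by 8.13 (3 of 4 deficient arrays well above background) and 6.63 on slide 1 and by 2.44 and 2.17 on slide 2, a difference between slides with adjusted p 0.000585 and 0.00218. Of the 3 probes nearest the 3'RR, the pair described as heavy chain of the J558 family fell by 3.46 and 3.59. The probe described as heavy chain complex was 11.5-fold lower on slide 1 and at least 4.32-fold lower on slide 2. The 1 probe that did not pass differed by -0.35 (adjusted p 0.0683) and has no description. The mu constant gene, which encodes the heavy chain of IgM, fell by 1.24 (SE 0.15, adjusted p 6.97e-05), with -0.54 on slide 1 (adjusted p 0.0791), -1.94 on slide 2 (adjusted p 4.11e-05) and a difference between slides with adjusted p 0.0095. The delta probe fell by 0.73 (SE 0.10, adjusted p 0.000271), with -1.53 on slide 1 and 0.07 on slide 2 (adjusted p 0.831). Its call over both slides was lost with slide as an additive block (adjusted p 0.053). Ighg, the 1 measured name of the fixed list of heavy chain constant genes, stands at a position among the variable segments and fell by 1.91 (SE 0.14, adjusted p 8.15e-07).

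Within slides, 11 of the 13 constant region probes fell on slide 1 (median -4.30) and 12 on slide 2 (median -4.32). Of the variable probes, 87 fell on slide 1 (median -1.61), and on slide 2 87 fell and 1 rose (median -2.51). With dim probes at their bound these medians were -1.58 and -2.43. With slide as an additive block the counts were again 12 and 90. No measured probe lay between Tmem121 and the first constant region probe (114427734 to 114496984). The deleted part itself was therefore not checked. Of 32 probes of genes flanking the locus, 5 were higher and 4 lower with a median of -0.01, and -0.05 with dim probes at their bound. Adam6a and Adam6b, genes that lie among the variable segments, were 2 of the lower ones, with Adam6b falling by 0.61 (adjusted p 0.000769). Over the 25 measured genes of the flanking list, 5 were higher and 4 lower both over all genes and adjusted over the list alone. The list had a negative median (-0.01) and mean (-0.04) beside an upward test with adjusted p 0.88, and Inf2, a formin that shapes actin filaments, rose by 0.37, with 0.61 and 0.13 on the slides. Of the fixed light chain list, Vpreb3 fell by 0.65 (SE 0.16, adjusted p 0.012) and Iglv1 differed by -0.04 (adjusted p 0.898; 0.65 and -0.74 on the slides).

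**Figure D1:**
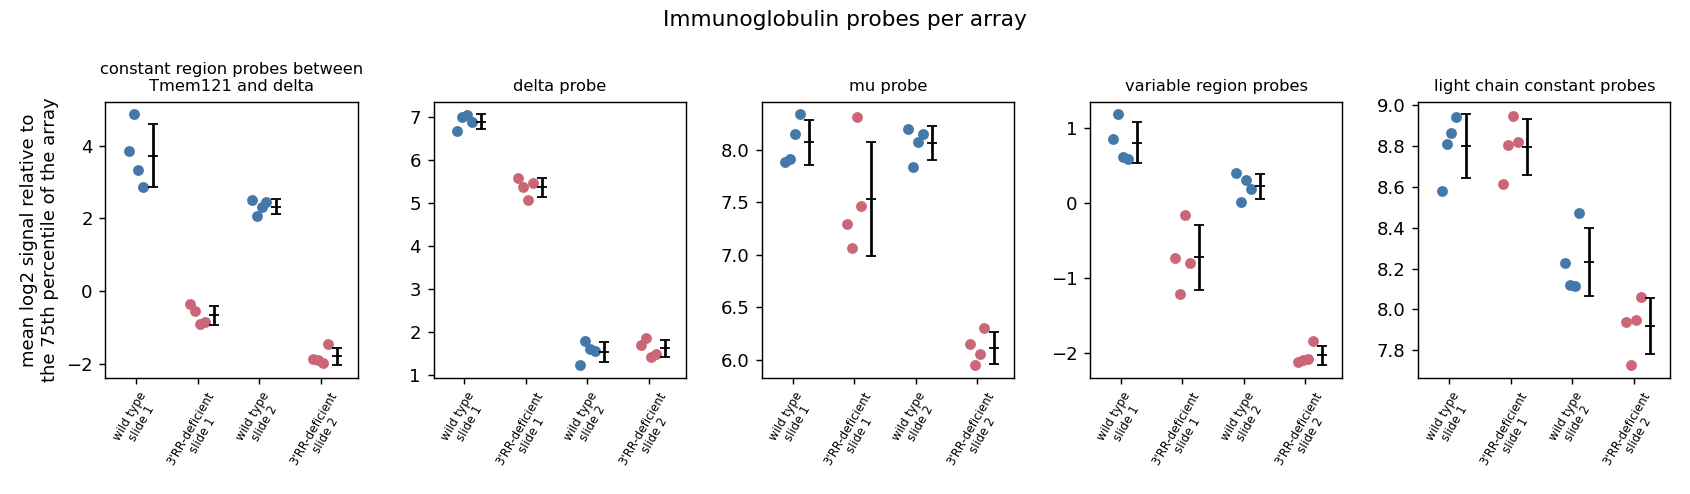
Mean log2 signal relative to the array's 75th percentile, per array, for the classes of immunoglobulin probes in the 4 groups of 4 arrays; points are arrays and bars are the group mean and standard deviation. The constant region probes between Tmem121 and delta lie between -1.99 and -0.36 in deficient arrays and between 2.06 and 4.86 in wild-type arrays, while light chain constant probes lie between 7.73 and 8.95 in all arrays.

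Outside the locus, the genes with the largest increase in deficient cells included Mnda, Oasl2 and Pydc4. Mnda, an interferon-inducible HIN-200 family gene, rose by 5.47 (SE 0.17, adjusted p 1.92e-10), with 15-fold on slide 1 and 130-fold on slide 2, where it was well above background on 1 of 4 wild-type arrays. Oasl2, an interferon-induced 2'-5' oligoadenylate synthetase-like gene, was at least 50.1-fold higher on slide 1 and 8.03-fold higher on slide 2 (adjusted p 2.48e-05 over both slides). Without deficient array 2 of slide 2 the latter fold, with 3 of 4 wild-type arrays well above background, was 4.25. Pydc4, which encodes a pyrin domain protein, was 38.9-fold higher on slide 1 and at least 2.28-fold higher on slide 2 (adjusted p 5.03e-09). Among the lowest was Ifi202b, another HIN-200 gene, at least 11.8-fold lower on slide 1 and well above background on 1 wild-type array of slide 2 (adjusted p 1.95e-07).

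In all, 1759 genes were higher and 2179 lower of 22677 tested (17.4%), and 340 and 314 of them at least 2-fold. Other genes with large increases were Sema5a, a semaphorin (at least 30.7-fold on slide 1 and at least 2.24-fold on slide 2, adjusted p 3.21e-09), Pou6f1, a POU-domain transcription factor (3.79, SE 0.10, adjusted p 3.22e-11), and Map7, a microtubule-associated protein (3.24, SE 0.25, adjusted p 9.82e-07; well above background on 3 and 1 of 4 wild-type arrays of slides 1 and 2). Camk2b, a subunit of a calcium- and calmodulin-dependent kinase, was at least 11.9-fold higher on slide 1 and 5.40-fold higher on slide 2. Car9, a carbonic anhydrase, was at least 5.56-fold and, with 3 of 4 deficient arrays well above background, at least 2.34-fold higher. Fzd6, a Wnt receptor with 3 of 4 deficient arrays well above background on each slide, was at least 3.47-fold (at least 2.25-fold without deficient array 9 of slide 1) and at least 2.62-fold higher, and Etohi1, a zinc finger gene, at least 1.72-fold (3 of 4 deficient arrays well above background) and at least 7.07-fold higher. Trim5 and Trim12a, neighbouring genes of the tripartite motif family on chromosome 7, passed over both slides with adjusted p 0.0201 and 0.0213. Trim12a was 200-fold higher on slide 1 (127-fold with dim arrays at their floor), with 3 of 4 deficient arrays and 1 of 4 wild-type arrays well above background, and at least 15.1-fold higher on slide 2, with 2 of 4. Trim5 was at least 9.97-fold and at least 1.98-fold higher with the same numbers of deficient arrays. With 1 deficient array of slide 1 left out, the slide 1 fold of Trim12a was 99.9, 116, 126 and 1100 without arrays 9, 11, 10 and 12. That of Trim5 was at least 5.7 without array 9 and at least 32.1 without array 12. On slide 2 neither passed (adjusted p 0.289 for Trim5 and 0.245 for Trim12a). The slide 2 bound was 47.9, 5.12, 38.1 and 5.49 for Trim12a, and 3.67, 1.07, 3.72 and 1.06 for Trim5, without deficient arrays 1, 2, 3 and 4 of that slide. The slide 1 call of Trim12a was lost without any 1 of 6 of the arrays, at adjusted p 0.061 to 0.089, the highest without deficient array 9 of slide 1.

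Of the lower genes, Itln1, an intestinal lectin, was at least 38.7-fold lower on slide 1 and 3.17-fold lower on slide 2 (adjusted p 1.18e-07). Rab4a, a small GTPase of endosome recycling, fell by 3.97 (SE 0.36, adjusted p 5.5e-06; -3.07 with dim arrays at their floor, where the slide 1 value moved from -3.58 to -2.02), Pxdn, a peroxidasin of the extracellular matrix, by 2.90 (SE 0.47, adjusted p 0.000932), and Gchfr, a regulator of GTP cyclohydrolase, by 2.73 (SE 0.38, adjusted p 0.000237). Vsig8, an immunoglobulin domain gene, was at least 5.23-fold and at least 6.47-fold lower. Olfr433, an olfactory receptor gene, was 12.6-fold lower on slide 1 and at least 2.51-fold lower on slide 2, and Lyplal1, a lysophospholipase-like gene, at least 1.73-fold and 7.75-fold lower. Arhgef16, a guanine nucleotide exchange factor, fell by 2.94 (adjusted p 0.0106), Gprc5b, an orphan receptor, by 2.87 (adjusted p 0.0233), Rgs18, a regulator of G-protein signalling, by 2.85 (adjusted p 0.0119) and Exd1, an exonuclease domain gene, by 2.78 (adjusted p 0.00146). Without deficient array 2 of slide 2 the value of Arhgef16 was -2.32, and without deficient array 9 of slide 1 that of Gprc5b was -2.10. The slide 1 value of Rab4a was -4.23 without deficient array 10 of that slide. Gprc5b passed on neither slide alone (adjusted p 0.105 and 0.103), and Arhgef16 passed on slide 1 (adjusted p 0.00911, and 0.073 with array weights). Rgs18 passed on slide 1 as well (adjusted p 0.0146, and 0.065 with that slide fitted alone). On slide 2 neither Arhgef16 (adjusted p 0.315) nor Rgs18 (0.243) passed. The slide 2 value of Rgs18 was -1.99, and -0.866 with dim arrays at their floor. With the authors' value table Gprc5b missed the threshold (adjusted p 0.051). Deficient arrays well above background on slides 1 and 2 numbered 1 and 2 of 4 for Rab4a, 2 and 3 for Arhgef16, 3 and 1 for Gprc5b and 2 and 1 for Rgs18. On slide 1 there were 1 for Pxdn and 2 each for Gchfr, Exd1 and Olfr433, and on slide 2 2 each for Itln1 and Lyplal1. With dim arrays at their floor Arhgef16 stood at -2.22 and Rgs18 at -1.84, and both passed (adjusted p 0.0047 and 0.0085). The split of calls depended on the scaling, with 44.7% higher at the 75th percentile and 59.1% when arrays were scaled by their median. With slide as an additive block 1234 genes were higher and 1422 lower, and with slide as a random block 982 and 1193.

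Interferon response genes rose together in deficient cells. Of 33 measured members, 26 rose and none fell (32 and 0 adjusted over the list alone), with a median of 1.00 and camera's adjusted p 5.4e-24, and adjusted p = 0.14 with an estimated correlation. Beside Mnda and Oasl2, Oas1a, an oligoadenylate synthetase that senses double-stranded RNA, rose by 2.29 (SE 0.24, adjusted p 2.16e-05) and Ifi203, a HIN-200 gene, by 1.12 (SE 0.08, adjusted p 6.01e-07), although 1 of 3 other probes of Ifi203 went the other way. On slide 1 the list median was 1.30 (27 higher, 1 lower) and on slide 2 0.47 (13 higher), and adjusted p = 0.22 and 0.42 with an estimated correlation. The shift was smaller on slide 2 (difference -0.54, adjusted p 0.00026, and adjusted p = 0.52 with an estimated correlation).

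Genes of the MHC class I pathway, which presents peptides of the cell's own proteins, also rose, with 11 of 21 higher and 0 lower (15 and 0 adjusted over the list alone), a median of 0.25 and adjusted p 3.4e-08, and adjusted p = 0.22 with an estimated correlation. H2-T9, a non-classical class I gene, rose by 0.99 (adjusted p 2.01e-05) and Tap1, a subunit of the peptide transporter, by 0.53 (adjusted p 0.00236). H2-Q7 rose by 0.38 (adjusted p 0.00251, with 0.72 and 0.04 on the slides) and H2-Q10 by 0.36 (adjusted p 0.00295). The call of H2-Q10 was lost with the mean over its probes (adjusted p 0.51). The median was 0.36 on slide 1 (12 higher, adjusted p 1.2e-09) and 0.12 on slide 2 (1 higher, adjusted p 0.18), and the slides differed by -0.29 (adjusted p 3.3e-05). With an estimated correlation adjusted p = 0.22 for slide 1 and 0.49 for that difference. MHC class II genes, which present antigen to helper T cells, did not pass as a list (0 higher and 1 lower of 13, the same adjusted over the list alone, median -0.07, adjusted p 0.24). H2-Aa fell by 0.23 (adjusted p 0.00148) and H2-Ob differed by -0.21 (adjusted p 0.0914).

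Early activation genes, among them transcription factors and phosphatases induced within minutes of B cell stimulation, were lower in deficient cells. Of 27 measured, 15 fell and 0 rose (17 and 1 adjusted over the list alone), with a median of -0.42 and adjusted p 9.4e-06, and adjusted p = 0.34 with an estimated correlation. Dusp1, a phosphatase that dampens MAP kinases, fell by 1.04 (SE 0.19, adjusted p 0.00199), Egr1, an immediate early transcription factor, by 0.84 (adjusted p 0.00189) and Dusp5 by 0.82 (adjusted p 0.00383; on slide 1 well above background on 1 of 4 deficient and 3 of 4 wild-type arrays). Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, fell by 0.69 (adjusted p 0.00454). On slides 1 and 2 the values were -1.71 and -0.37 for Dusp1 and -1.21 and -0.18 for Nr4a1. The median was -0.82 on slide 1 (18 lower, adjusted p 3.9e-06) and -0.04 on slide 2 (1 higher, 3 lower, adjusted p 0.21), and the slides differed by 0.59 (adjusted p 0.0058). With an estimated correlation adjusted p = 0.39 for slide 1 and 0.52 for the difference. Heat shock genes, which encode chaperones, had 2 of 10 lower and 0 higher (the same adjusted over the list alone) with a median of -0.21 and adjusted p 0.031, and adjusted p = 0.63 with an estimated correlation. Dnajb1 fell by 0.28 (adjusted p 0.00873) and Hsp90aa1 by 0.26 (adjusted p 0.0237), with -0.64 and 0.08 on the slides for Dnajb1 and -0.66 and 0.14 for Hsp90aa1. Hsph1 differed by -0.34 (adjusted p 0.0893) and Hspb1 by -0.74 (adjusted p 0.125). The heat shock list fell on slide 1 (7 lower, median -0.42, adjusted p 0.0018) and not on slide 2 (1 higher, median 0.10 beside a mean of -0.03, adjusted p 0.57), a difference of 0.72 (adjusted p 0.0037). With an estimated correlation adjusted p = 0.43 on slide 1 and 0.52 for the difference. Its call over both slides was lost with slide as an additive block (adjusted p 0.1) and without deficient array 11 of slide 1 (0.073), wild-type array 5 of slide 1 (0.11) or deficient array 2 of slide 2 (0.052), and the additive block also ended the calls of Dnajb1 (0.13) and Hsp90aa1 (0.2).

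The list of transitional and immature B cell markers was lower. It also holds genes of earlier bone marrow stages, among them Il7r and Myb, and is no count of the cells that enter the spleen. Of 8 measured, 5 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.54 and adjusted p 0.0045, and adjusted p = 0.34 with an estimated correlation. Il7r, the receptor for interleukin 7, fell by 0.86 (SE 0.18, adjusted p 0.00521) and Vpreb3, a protein bound to immature receptor chains, by 0.65. Myb, a transcription factor of progenitors, fell by 0.55 (adjusted p 0.0281) and Cd24a by 0.53 (adjusted p 0.0201). The call of Myb was lost without any 1 of 7 of the arrays (adjusted p 0.051 to 0.057, the highest without deficient array 4 of slide 2). It was also lost with slide as an additive block (adjusted p 0.056). The list median was -0.39 on slide 1 (2 lower, adjusted p 0.2) and -0.69 on slide 2 (3 lower, adjusted p 0.00069, and adjusted p = 0.4 with an estimated correlation). The difference between slides did not pass (adjusted p 0.24). Without the filter on dim probes the call over both slides was lost (adjusted p 0.13).

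Cell cycle genes were higher as a list, with 7 of 27 higher and 1 lower (11 and 1 adjusted over the list alone), a median of 0.31 and adjusted p 3.5e-05, and adjusted p = 0.63 with an estimated correlation. Nusap1, a mitotic spindle protein, rose by 0.85 (SE 0.16, adjusted p 0.00236), Ccnb1, a mitotic cyclin, by 0.48 (adjusted p 0.0305) and Plk1, a mitotic kinase, by 0.48 (adjusted p 0.0262). Pcna, a clamp for DNA polymerase, fell by 0.29 (adjusted p 0.0055; -0.53 and -0.05 on the slides). Without any 1 of 9 of the arrays Ccnb1 lost its call (adjusted p 0.051 to 0.062) and without any 1 of 5 Plk1 did (0.05 to 0.054). Each had its highest value without deficient array 1 of slide 2. Ccnb1 also lost its call with slide as an additive block (0.076), the mean over probes (0.072) and the authors' value table (0.053), among other settings. Fry, which sets the list against no other genes, gave adjusted p 0.12. The median was 0.52 on slide 1 (12 higher, 1 lower, adjusted p 3.9e-06) and 0.11 on slide 2 (0 higher and 0 lower by limma's test, 1 and 0 at an unadjusted p under 0.05, list adjusted p 0.4), a difference of -0.34 (adjusted p 0.0021). With an estimated correlation adjusted p = 0.56 on slide 1 and 0.65 for this difference.

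Lists of other mature B cell functions did not pass over both slides with camera. With fry, B cell receptor signalling (adjusted p 0.019), B cell transcription factors (0.039) and marginal zone markers (0.019) passed. B cell receptor signalling genes had 4 of 24 higher and 2 lower (the same adjusted over the list alone), with a median of -0.01 beside a mean of 0.11 and an upward test (adjusted p 0.47). On slide 1 they had 0 higher and 6 lower (median -0.14, adjusted p 0.2) and on slide 2 3 higher and 0 lower (median 0.14, adjusted p 0.0035), a difference of 0.26 (adjusted p 0.0017). The estimated correlation gave adjusted p = 0.13 on slide 2 and 0.091 for the difference. Fcgr2b, the inhibitory Fc receptor of B cells, rose by 1.33 (SE 0.07, adjusted p 1.8e-08), with -0.03 on slide 1 and 2.70 on slide 2 (difference adjusted p 1.32e-07), and Cd81, a tetraspanin, fell by 0.34 (adjusted p 0.00363). B cell transcription factors had 4 of 18 higher and 1 lower (the same adjusted over the list alone, median 0.07, adjusted p 0.12), with Bach2, a repressor of plasma cell fate, up by 0.67 (adjusted p 0.000329) and Pou2f2, the octamer factor Oct-2, up by 0.37 (adjusted p 0.000957). Follicular B cell markers had 2 of 11 higher and 3 lower (3 and 4 adjusted over the list alone, median -0.19, adjusted p 0.98), with Fcrl1 up by 1.06 (adjusted p 5.8e-05) and Cd200 down (-0.66, adjusted p 0.00023). On the slides Fcrl1 stood at 0.35 and 1.77 and Cd200 at -1.08 and -0.25. The follicular median was -0.46 on slide 1 (0 higher, 2 lower, adjusted p 0.093) and 0.105 on slide 2 (5 higher, 0 lower, adjusted p 0.11), a difference of 0.69 (adjusted p 0.0017, and adjusted p = 0.45 with an estimated correlation). Marginal zone markers had 1 of 14 higher and 5 lower (2 and 5 adjusted over the list alone, median -0.12, -0.10 with dim members at their bound, adjusted p 0.23). Cd9, a tetraspanin, fell by 0.78 (adjusted p 0.000129) and Cd36, a scavenger receptor, by 1.34 (adjusted p 0.000984), with -0.76 and -0.80 on the slides for Cd9 and -1.33 and -1.36 for Cd36. B-1 cell markers had 2 of 13 higher and 1 lower (the same adjusted over the list alone, median 0.15, adjusted p 0.34), with Zbtb32 up by 1.08 (adjusted p 0.000332; 1.84 and 0.32 on the slides) and Zcwpw1 down (-0.51, adjusted p 0.0153).

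Germinal centre and class switch genes had 1 of 17 higher and 1 lower (the same adjusted over the list alone, median 0.10, adjusted p 0.34). Ung, the uracil glycosylase that acts in class switching, fell by 0.38 (adjusted p 0.0165). Plasma cell genes, which serve antibody secretion, had 0 of 20 higher and 1 lower over both slides (the same adjusted over the list alone, median -0.02, 0.02 with dim members at their bound, adjusted p 0.98). The slides went opposite ways, with 7 higher and 1 lower on slide 1 (median 0.41, adjusted p 0.00029) and 0 higher and 6 lower on slide 2 (median -0.30, adjusted p 4.8e-06), and adjusted p = 0.56 and 0.63 with an estimated correlation. The difference was -0.75 (adjusted p 3.6e-08, and adjusted p = 0.49 with an estimated correlation). Irf4, a transcription factor of plasma cells, fell by 0.47 over both slides (adjusted p 0.0093), and Creld2, a chaperone-like protein, differed by 0.45 (adjusted p 0.112), with 1.04 on slide 1 and -0.15 on slide 2. Toll-like receptor genes had 3 of 19 higher and 2 lower (the same adjusted over the list alone, median 0.02, adjusted p 0.22), with Irak4, a kinase of that pathway, up by 0.56 (adjusted p 7.27e-05) and Traf6 down (-0.28, adjusted p 0.0136, with 1 of 2 other probes going the other way). Survival and apoptosis genes had 1 of 26 higher and 2 lower (the same adjusted over the list alone), with a negative median (-0.00381, and 0.03 with a dim member at its bound), a positive mean (0.000745) and an upward test (adjusted p 0.88). In that list Traf1 rose by 0.45 (adjusted p 0.00495) and Bax, a death effector, fell by 0.21 (adjusted p 0.0101). Oxidative phosphorylation genes had 2 of 36 lower and 0 higher (0 and 0 adjusted over the list alone, median -0.04, adjusted p 0.34). Uqcrb fell by 0.18 (adjusted p 0.0331) and Sdhb by 0.21 (adjusted p 0.0483), calls lost without any 1 of 9 arrays (0.052 to 0.068) and of 14 arrays (0.051 to 0.09), each with the highest value without deficient array 4 of slide 2. Slide as an additive block also ended the calls of Uqcrb (adjusted p 0.13) and Sdhb (0.2). On the slides Uqcrb stood at -0.37 and 0.01 and Sdhb at -0.50 and 0.08. The list was lower on slide 1 (14 lower, median -0.22, adjusted p 6.4e-05) and higher on slide 2 (3 higher, median 0.13, adjusted p 9e-04), and adjusted p = 0.58 and 0.83 with an estimated correlation. The slides differed by 0.36 (adjusted p 1.1e-07, and adjusted p = 0.52 with an estimated correlation).

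**Figure D2:**
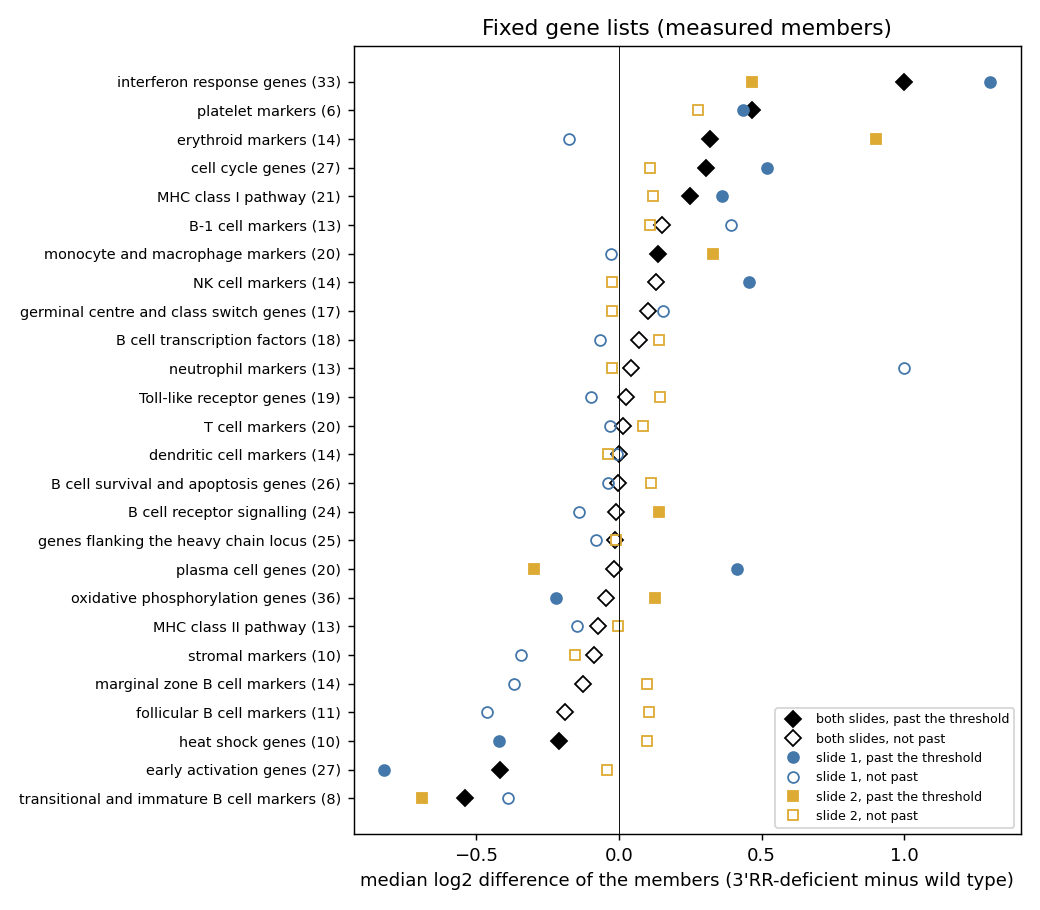
Median log2 difference, deficient minus wild type, of the 26 fixed gene lists over both slides (diamonds), on slide 1 (circles) and on slide 2 (squares), from 4 arrays per genotype and slide; filled symbols passed camera's adjusted p of 0.05 and open ones did not. Interferon response genes lie at 1.30 on slide 1 and 0.47 on slide 2, erythroid markers at -0.17 and 0.90 (0.33 with dim members at their bound), and plasma cell genes at 0.41 and -0.30.

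Markers of other blood cells moved with genotype in part. Erythroid markers had 4 of 14 higher and 0 lower (the same adjusted over the list alone), with a median of 0.32 and adjusted p 0.0045, and adjusted p = 0.63 with an estimated correlation. The 4 were the globin genes, with Hba-a2 up by 2.36 (adjusted p 0.000655) and Hba-a1 up by 2.23 (adjusted p 0.00237). Hbb-b1 (adjusted p 0.000745) and Hbb-b2 (adjusted p 0.0015) were at least 33.7-fold and at least 22.5-fold higher on slide 2, and none of the 4 passed on slide 1. The erythroid median was -0.17 on slide 1 (adjusted p 0.93) and 0.90 on slide 2 (5 higher, adjusted p 0.00019, and adjusted p = 0.63 with an estimated correlation). With dim members at their bound it was 0.33 on slide 2 and 0.12 over both slides. The slides differed by 0.93 in fitted values (adjusted p 0.0087, and adjusted p = 0.52 with an estimated correlation). With slide as an additive block, the list (adjusted p 0.053) and the 4 globin genes (0.065 to 0.19) no longer passed. Platelet markers had 2 of 6 higher and 0 lower (the same adjusted over the list alone, median 0.47, 0.46 with dim members at their bound, adjusted p 0.015, and adjusted p = 0.2 with an estimated correlation). Clec1b, a platelet receptor, rose by 1.63 (adjusted p 7.57e-06), with 3.14 on slide 1 (2 of 4 wild-type arrays well above background), 0.12 on slide 2 (adjusted p 0.811) and a difference between slides with adjusted p 0.000111. Itgb3, an integrin, rose by 1.00 (adjusted p 0.00172). Pf4 differed by 0.59 (adjusted p 0.184) and Treml1 by 0.35 (adjusted p 0.265). The platelet median was 0.43 on slide 1 (2 higher, adjusted p 0.029, and adjusted p = 0.23 with an estimated correlation) and 0.28 on slide 2 (1 higher, adjusted p 0.32). Monocyte and macrophage markers had 3 of 20 higher and 0 lower (the same adjusted over the list alone, median 0.14, 0.18 with dim members at their bound, adjusted p 0.018, and adjusted p = 0.63 with an estimated correlation). Cd5l, a macrophage scavenger protein, rose by 3.12-fold on slide 1 and at least 8.76-fold on slide 2, Lyz1 by 1.17 (adjusted p 0.00707; well above background on 2 of 4 wild-type arrays of slide 2) and Fcgr3 by 0.64 (adjusted p 6.22e-06), with -0.56 on slide 1 and 1.84 on slide 2 for Fcgr3. Mpeg1 differed by 0.24 (adjusted p 0.121). The call of the macrophage list was lost without deficient array 11 (0.11) or wild-type array 5 of slide 1 (0.22), with slide as an additive block (0.053), and for Fcgr3 with that block (0.21). The macrophage median was -0.03 on slide 1, where mean (0.16) and test were upward (adjusted p 0.46), and 0.33 on slide 2 (3 higher, adjusted p 0.012, and adjusted p = 0.72 with an estimated correlation).

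T cell markers had 2 of 20 higher and 1 lower (the same adjusted over the list alone, median 0.01, 0.00175 with dim members at their bound, adjusted p 0.52). Lat fell by 0.55 (adjusted p 0.0133). Cd3g, 1 of the 2 counted as higher (adjusted p 0.00611), differed by 0.37 on slide 1 (adjusted p 0.428) and was not well above background on any array of slide 2, so its call rests on values below background (adjusted p 0.26 with dim arrays at their floor). NK cell markers had 2 of 14 higher and 0 lower (the same adjusted over the list alone, median 0.13, 0.28 with dim members at their bound, adjusted p 0.23). They passed on slide 1 (2 higher, median 0.46, adjusted p 0.027) and not on slide 2 (1 lower, median -0.03, -0.06 with dim members at their bound, adjusted p 0.69), a difference of -0.47 in fitted values (adjusted p 0.02). For slide 1 and the difference, adjusted p = 0.56 and 0.52 with an estimated correlation. Il2rb rose by 0.59 (adjusted p 0.00465; 1.06 and 0.13 on the slides), and Klra7 was 2.61-fold higher on slide 1 (adjusted p 0.0324 over both slides), not well above background on any array of slide 2 and lost with dim arrays at their floor (0.06) and without any 1 of 11 arrays (0.05 to 0.066, the highest without deficient array 1 of slide 2). Neutrophil markers had 0 of 13 past the threshold of limma's test in either direction, also adjusted over the list alone (median 0.04, -0.06 with dim members at their bound, adjusted p 0.59). At an unadjusted p under 0.05 1 was higher and 0 were lower. Retnlg stood at 2.37 on slide 1 (adjusted p 0.036 there and 0.105 over both slides; 1.75 and 2.98 without deficient arrays 11 and 12) and S100a8 at 1.63 (adjusted p 0.199 and 0.277), neither well above background on slide 2. The S100a8 value was 0.77 and 2.29 without deficient arrays 11 and 12 of slide 1, and 0.97 without wild-type array 6. Dendritic cell markers had 1 of 14 higher and 1 lower (the same adjusted over the list alone), with a median of 0.00256 (0.00625 with dim members at their bound), a mean of -0.15 and an upward test (adjusted p 0.94). Flt3 rose by 0.49 (adjusted p 0.0109), and Cd209a was 2.91-fold lower on slide 1 (adjusted p 0.00814 over both slides; well above background on 1 array of slide 2). Stromal markers had 1 of 10 higher and 0 lower (0 and 0 adjusted over the list alone, median -0.09, -0.37 with dim members at their bound, adjusted p 0.88). Ccl19 rose by 0.52 (adjusted p 0.0391), a call lost without any 1 of 11 arrays (0.052 to 0.082, the highest without wild-type array 1 of slide 2). Its call was also lost with slide as an additive block (0.1) and with normexp (0.16), among other settings. Bgn differed by -0.46 (adjusted p 0.0695). With camera's preset correlation 9 of 26 fixed lists passed the threshold over both slides. With the estimated one 0 did (3 at an unadjusted p under 0.05), and with fry 9 did. These were not the same 9, since fry lost the cell cycle, macrophage and erythroid lists. It gained B cell receptor signalling, B cell transcription factors and marginal zone markers. On slide 1, on slide 2 and for the difference between slides camera's preset correlation passed 9, 7 and 11 lists, and the estimated correlation 0. At an unadjusted p under 0.05 the latter gave 3, 3 and 2. Fry passed 11, 9 and 10 lists.

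Within slide 1, 2087 genes were higher and 3484 lower in deficient cells, and within slide 2, 996 were higher and 923 lower. Among those changed at least 2-fold the balance turned, with 784 higher and 443 lower on slide 1 and 238 and 448 on slide 2. The order of the slides depended on the fit. Arrays spread less within groups on slide 2, while the main fit shares 1 estimate of the spread. The median standard deviation over genes was 0.202 (deficient) and 0.214 (wild type) on slide 1, against 0.138 and 0.152 on slide 2. With each slide fitted alone, slide 1 had 898 higher and 1251 lower and slide 2 had 1484 higher and 1463 lower, and array weights called 3674 higher and 2544 lower on slide 2. Among genes with an official symbol, which leaves out the heavy chain constant probes, the largest increases by fitted difference on slide 1 were those of Trim12a, Oasl2, Sema5a, Pydc4 and Tcstv3 (at least 16.9-fold, adjusted p 2.14e-06), and the largest decreases those of Itln1, Ifi202b, Arhgef16, Rgs18 and Olfr433. On slide 2, with the same limit, the largest increases were those of Mnda, Mpzl2, an adhesion molecule (58.9-fold, adjusted p 1.27e-08; well above background on 3 of 4 wild-type arrays), Hbb-b1, Hbb-b2 and Hba-a2, and the largest decreases those of Rab4a, Hspb2, a small heat shock protein (at least 4.8-fold, adjusted p 1.61e-05), Gchfr, Vsig8 and the variable segment Ighv6-6 (11.3-fold, adjusted p 4.57e-07). Genes higher on both slides numbered 287, against 91.66 for independent lists of those sizes, and genes lower on both 336, against 141.8. Higher on slide 1 and lower on slide 2 were 72, against 84.95, and the reverse 128, against 153. The slides' calls share 1 estimate of the spread, so they are not independent lists. Across all genes the differences of the slides correlated with r = 0.293, where genes are not independent replicates. Of the 3938 genes past the threshold over both slides, 3440 had 1 sign on both slides and 1104 differed between slides. The share of higher calls on slide 1 was 37.5%, against 48.1% with the authors' value table and 91% with scaling by the positive controls. On slide 2 it was 51.9%, against 40.9% with quantile scaling, 67.2% with median scaling, 41.5% with the authors' value table and 12.2% with the positive controls. Without wild-type array 5 of slide 2, positive controls gave 96.3% and 33.5%. Relative to the 75th percentile, median scaling moved the median difference of all genes to 0.11 on slide 2 and positive control scaling to 0.35 on slide 1 and -0.49 on slide 2. Over both slides that last scaling called 296 genes higher and 328 lower, and 5463 and 634 without that array. The 996 higher genes of slide 2 became 522, 663 and 612 without wild-type arrays 1, 2 and 3 of that slide and 613 and 629 without deficient arrays 1 and 2, and the 923 lower became 562 without wild-type array 1.

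The difference between genotypes itself differed between slides for 3640 genes, 2416 of them with a higher value on slide 2 and 1224 with a lower one. Among genes with an official symbol, globin genes led the former, with fitted differences of 7.24 for Hbb-b2, 6.87 for Hbb-b1, 5.45 for Hba-a2 and 5.40 for Hba-a1, together with Mpzl2 at 6.25. Fitted values of genes dim in a whole group, here Hbb-b1, Hbb-b2 and Mpzl2, rank the genes and are no measured folds. The latter were led by Klri2, an NK cell receptor gene (-5.20, adjusted p 0.000338), Tcstv3 (-5.19), Aldh1a2, a retinoic acid-forming enzyme (-4.77, adjusted p 0.000756; well above background on 1 of 4 wild-type arrays of slide 1), Ntn5, a netrin (-4.35, adjusted p 0.0449), and Dmrt2, a transcription factor (-4.31, adjusted p 0.0232). Klri2 and Tcstv3 were not well above background on slide 2 in either genotype. Ntn5 and Dmrt2 were not in wild-type arrays of slide 1, nor Dmrt2 in deficient arrays of slide 2, so their fitted values are no measured folds either. The call of Ntn5 was lost without any 1 of 13 arrays (0.056 to 0.085, the highest without deficient array 9 of slide 1), and those of Ntn5 and Dmrt2 with quantile scaling (0.054 and 0.053), and that of Dmrt2 with dim arrays at their floor (0.084). Of these calls 66.4% were higher, against 47.5% with quantile scaling, 45.8% with the authors' value table and 2.17% with the positive controls (2.27% without wild-type array 5 of slide 2). Among calls of at least 2-fold, 244 were higher and 749 lower (24.6% higher). Position on the slide is exchanged between genotypes from slide to slide, so this comparison cannot separate position from slide.

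**Figure D3:**
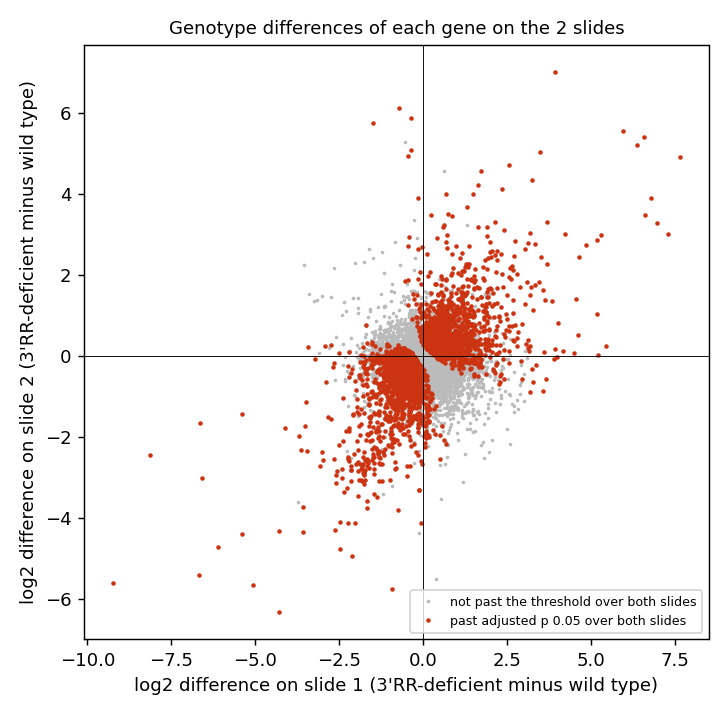
Log2 difference, deficient minus wild type, of each of 22677 genes on slide 1 (horizontal axis) and slide 2 (vertical axis), from 4 arrays per genotype on each slide; red points passed an adjusted p of 0.05 over both slides and grey points did not. The differences correlate with r = 0.293 across genes.

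Genes differed far more between the slides than between genotypes, with 12101 higher and 6562 lower on slide 2. Of 20 monocyte and macrophage markers 20 were lower on slide 2 (20 adjusted over the list alone, median -5.66, adjusted p 2.5e-12, and adjusted p = 0.071 with an estimated correlation). Of 20 T cell markers 16 were lower (median -2.35, -2.08 with dim members at their bound, adjusted p 3.7e-07, and adjusted p = 0.041 with an estimated correlation). Marginal zone markers were lower in 12 of 14 (median -1.73, adjusted p = 0.041 with an estimated correlation), and all 27 cell cycle genes were higher (median 2.49, adjusted p 1.9e-07, and adjusted p = 0.38 with an estimated correlation). The labels give the same tissue and sorting for both slides and name no difference between them. The share of higher genes was 64.8%, against 49.3% with median scaling and 76% with the positive controls (65.3% without wild-type array 5 of slide 2).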

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

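The tests of plasma cell genes and of light chain probes for the heavy chain pattern were chosen after that result was seen. The term for Y-linked signal was chosen after the data were seen. The other tests of this part were set before theirs, but the rule on a common offset of the positive controls was not.

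The fall of heavy chain constant probes was weighed against a smaller share of plasma cells and against the scaling of whole arrays. On slide 1 the median of the plasma cell genes was 0.413, above 0 while the constant probes fell. The list thus gave no sign of fewer plasma cells there, with camera's adjusted p = 0.56 for its rise at an estimated correlation. These genes serve antibody secretion and are no count of plasma cells, so a smaller share is not excluded on slide 1. On slide 2 that median was -0.296 with members going down, so on slide 2 fewer plasma cells may have contributed and the test does not decide. Kappa and lambda constant probes, with medians of -0.0723 on slide 1 and -0.339 on slide 2, moved too little for a scaling error to account for the fall on either slide. They add little, since the arrays were already scaled and all genes had median differences of -0.0758 on slide 1 and 0.0222 on slide 2. A shift of whole arrays as large as the fall was thus hardly possible beforehand. The light chain probes were also far brighter than the heavy chain constant probes. By the labels the heavy chain locus is of 129 origin in both genotypes, so strain differences in sequence under these probes are not expected, while the loss of the 3'RR and strain elsewhere in the genome remain open, and the labels do not let them be told apart.

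The genes that changed over both slides were weighed against chance, strain and base differences under probes. Of 100 splits drawn from 2450, 1 gave as many genes, the real one with 3938, and the highest other gave 674. This argues against chance, although 1 of 100 is the smallest share these splits can give. Within slide 1 it was 1 of 35 splits (5571 genes, highest other 246) and within slide 2 1 of 35 (1919, highest other 1), again the smallest share possible. The other splits mix the genotypes, so a real difference adds to their spread and lowers their counts. The gap to the highest other count therefore does not measure how unlikely chance is. For 1226 called genes with another measured probe, the median ratio of that probe's difference to the called one's was 0.768 (95% interval 0.728 to 0.804), which argues against base differences under single probes as the whole cause, although 25.5% had a ratio under 0.25. Strain stays open. The odds ratio of a call within 20 Mb of the heavy chain locus against elsewhere was 0.907 (95% interval 0.619 to 1.3), which includes 1 and decides nothing, and the labels do not separate strain from genotype.

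The difference between slides was weighed against chance, array position and sex-linked signal. Of 100 splits 1 gave as many genes, the real one with 3640, and the highest other gave 1373. The other splits mix the genotypes, so the difference common to both slides adds to their spread. The exchange of 1 slide's groups, which turns this comparison into the one over both slides, was not among those drawn. The splits therefore cannot exclude chance for the difference between slides. The 10 positive control transcripts, added to every RNA, differed between genotypes by slide by a median of 0.903 against 0.605 for called genes, a ratio of 1.49 (0.752 without wild-type array 5 of slide 2), but the 7 well above background moved almost alike, by 0.876 to 1.01. By the mark set beforehand a ratio this high counted for position as the cause, and that mark was set aside. An offset common to the controls, which unequal amounts of control RNA would also give, decides nothing about genes that moved both ways. Position, exchanged between the genotypes from slide to slide, cannot be told apart from the difference itself. With Y-linked signal as a term 4174 genes were called, which argues against the unequal number of arrays with such signal as the cause.

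Single arrays lay far from the other 3 of their group in 22 of 436 groups tested, where chance gives about 1 in 20. Wild-type array 5 of slide 2 had a 75th percentile of signal of 596.24 (others 890 to 948), a mean of the positive controls of 1.31 (others 3.18 to 3.29) and H2-Q7 at 7.97. The other values are log2 signals relative to the array's 75th percentile. Among deficient arrays of slide 1, array 12 had Trim12a at -4.55 (others 4.81 to 5.82) and Ung at 5.85 and array 10 had Mnda at 1.29. Among wild-type arrays of slide 1, array 5 had Oasl2 at -4.23 and array 8 had Fcgr3 at 2.06. Among deficient arrays of slide 2, array 4 had the mean of the variable region probes at -1.84, Map7 at -0.441, Gprc5b at -3.72 and Hba-a1 at 3.08. Array 2 of that group had Arhgef16 at -6.07, Fcrl1 at 1.06 and Hspb1 at -2.85, array 1 had Mpzl2 at 2.41, and array 3 had Hsp90aa1 at 7.02. Among wild-type arrays of slide 2, array 2 had Aldh1a2 at -0.749, Plk1 at 4.86 and Itgb3 at 2.92, and array 3 had Camk2b at -4.26 and Inf2 at 6.65.

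For 42 of 101 named genes the fitted difference between genotypes differed between slides past the threshold of limma's test of that difference. On the log2 scale and as slide 2 minus slide 1, it was 3.11 for Mnda, -4.28 for Oasl2, -3.69 for Sema5a, -2.29 for Pydc4, -2.13 for Pou6f1, 2.17 for Etohi1, -2.20 for Camk2b and 1.79 for Map7. It was 5.00 for Itln1, 3.98 for Ifi202b, -5.19 for Tcstv3, 6.87 for Hbb-b1, 7.24 for Hbb-b2, 5.45 for Hba-a2, 5.40 for Hba-a1 and 6.25 for Mpzl2. It was -4.07 for Hspb2, -2.11 for Ighv6-6, -5.20 for Klri2, -4.77 for Aldh1a2, -4.35 for Ntn5, -4.31 for Dmrt2, -1.39 for Iglv1 and -0.472 for Inf2. Among list members it was 2.72 for Fcgr2b, 1.42 for Fcrl1, 0.828 for Cd200, -1.52 for Zbtb32, -1.19 for Creld2, 0.487 for Pcna, 1.34 for Dusp1 and 1.03 for Nr4a1. It was 0.719 for Dnajb1, 0.799 for Hsp90aa1, 0.924 for Hsph1, -0.676 for H2-Q7, 0.373 for Uqcrb, 0.574 for Sdhb, -0.927 for Il2rb, 2.59 for Cd5l, 2.40 for Fcgr3 and -3.02 for Clec1b. Members dim in a whole group enter these fits with values that are no bounds.

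As medians of fitted values of lists, with no member at a bound, the difference between slides was 0.26 for B cell receptor signalling, 0.688 for follicular markers, -0.75 for plasma cell genes, -0.339 for cell cycle genes, 0.587 for early activation genes and 0.716 for heat shock genes. It was -0.537 for interferon response genes, -0.289 for the MHC class I pathway, 0.361 for oxidative phosphorylation, -0.471 for NK cell markers and 0.926 for erythroid markers. Of the heavy chain probes, it was -1.41 for mu, 1.60 for delta, 1.39 for gamma 3, 5.69 and 4.46 for the pair of gamma 1 probes, and -4.84 for the probe without a description that was dim in both genotypes on slide 1.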

How the results depend on the processing

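Scaling by positive controls, dim arrays at their floor, the term for Y-linked signal and leaving out chromosomes X and Y were chosen after seeing the data, the other alternatives before. Over the settings other than single arrays left out, 2683 results kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 266 lost their call, 30 gained one, 23 reversed and 44 moved. With 1 array left out 3254, 102, 24, 22 and 6 did. The cause was not tested except where fewer genes or arrays, or another threshold, made the change. No named gene that passed changed sign under another scaling. Of 128 calls of genes the rule takes 58 were lost with positive controls, and of 98 over both slides 22 with an additive slide term, 35 with a random block and 74 with no slide term. Any other setting ended at most 10. Few arrays per group limit the precision, and probes near background limit it on slide 2 for markers of other cells.

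With a 2-fold threshold, 340 genes were higher and 314 lower over both slides, 784 and 443 on slide 1, 238 and 448 on slide 2, 244 and 749 for the difference between slides and 6215 and 3107 between slides. Genes higher on slide 2 numbered 654 with quantile scaling, 559 with the authors' value table, 643 without a filter on dim probes and 3674 with array weights, which called 2544 lower. Genes with a higher difference on slide 2 numbered 1041, 1221, 1446 and 4121 in that order, and 1962 had a lower one with array weights. Without the filter, which adds genes, 10778 genes were lower between slides. Median scaling called 1311 lower over both slides. With positive controls, 296 were higher and 328 lower over both slides, 917 and 91 on slide 1, 98 higher on slide 2, 31 had a higher difference on slide 2, and 3397 were lower between slides. Without wild-type array 5 of slide 2 these became 5463 and 634, 9728 and 378, 319, 99 and 6263. An additive slide term called 1422 lower over both slides, a random block 982 higher and 1193 lower, and no slide term 189 and 195, with 6 of the downstream constant probes lower and 3 lists past the threshold. Fitted alone, with its own estimate of the spread, slide 1 gave 898 higher and 1251 lower and slide 2 gave 1484 and 1463. Fewer arrays do not account for the rise on slide 2, where the spread within groups was smaller.

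The delta probe lost its call over both slides with positive controls (-0.768, adjusted p 0.25) and, at -0.727, with an additive term (adjusted p 0.053), a random block (0.14) and no slide term (1). On slide 2 it turned to -0.015 with the value table and -0.438 with positive controls. With the mean over probes Gna13 turned to -0.0588 and Tcf4 to -0.0967, neither past the threshold. Of lists past the threshold, adjusted p rose to 0.066 for erythroid markers with the value table, 0.13 for transitional markers without the filter, 0.16 for macrophage markers with probes above background on all arrays and 0.14 with array weights, and 0.07 for heat shock genes with positive controls. With an additive term it was 0.1 for heat shock genes and 0.053 for macrophage and for erythroid markers. With no slide term it was 0.15 for transitional markers, 0.16 for cell cycle genes, 0.11 for heat shock genes, 0.41 for macrophage, 0.16 for erythroid and 0.066 for platelet markers. With an estimated correlation 0 lists passed, at 0.34 for transitional markers and early activation genes, 0.63 for cell cycle, heat shock, macrophage and erythroid lists, 0.14 for interferon response genes, 0.22 for MHC class I and 0.2 for platelet markers. With fry it was 0.12 for cell cycle genes and for macrophage markers and 0.054 for erythroid markers. Fry gained calls for B cell receptor signalling (adjusted p 0.019), B cell transcription factors (0.039) and marginal zone markers (0.019).

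Lists that did not pass over both slides turned direction there with these adjusted p. They were follicular markers with normexp (0.91), array weights (0.96) and the Y-linked term (0.87), and plasma cell genes with normexp (0.69), the value table (0.91), probes above background on all arrays (0.99), array weights (1) and dim arrays at their floor (0.95). Survival genes did with quantile scaling (0.99) and fry (0.94), and dendritic markers with median scaling (0.91), the mean over probes (0.64), positive controls (0.56) and fry (0.97). Neutrophil markers did with probes above background on all arrays (1) and the Y-linked term (0.95), stromal markers without X and Y (0.96), and the flanking list with positive controls (0.86) and no slide term (0.87).

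With 1 array left out, genes higher on slide 2 ranged from 522 to 1124 and lower from 562 to 1061, the adjusted p of the heat shock list from 0.0083 to 0.11 and that of macrophage markers from 0.0025 to 0.22. Iglv1 over both slides ranged from -0.188 to 0.0335 and the delta probe on slide 2 from -0.0303 to 0.157. Lists that turned direction had adjusted p from 0.77 to 1 for follicular markers, 0.37 to 1 for plasma cell genes, 0.65 to 1 for survival genes, 0.69 to 1 for dendritic markers and 0.15 to 1 for neutrophil markers.

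On slide 2, deviations of arrays with the same number correlated across genes with r = 0.0109, 0.124 and 0.0677. Arrays with unlike numbers gave -0.188 to 0.17. These values gave no clear sign that the numbers pair the arrays, and they do not exclude it. With the replicate block on those arrays 482 genes were higher and 744 lower, and without it on the same arrays 1398 and 1343. No pairing could be made on slide 1, where the genotypes share no numbers.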

Other observations

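Every gene, region and level of this part was chosen after the values were seen, and no test of regions was made.

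On slide 2 transcripts of dividing cells were higher than on slide 1, over both genotypes, although the list of cell cycle genes did not pass with an estimated correlation (adjusted p = 0.38). Mki67, a marker of dividing cells, was higher by 2.09 on the log2 scale (limma's adjusted p 1.81e-07). Cr2, a complement receptor of resting follicular and marginal zone B cells, fell by 6.62 (adjusted p 1.92e-15). Lists of Toll-like receptor genes, B cell transcription factors and MHC class II genes were lower on slide 2 in 12 of 19, 13 of 18 and 11 of 13 members and higher in 3, 2 and 1. With an estimated correlation their adjusted p = 0.046, 0.046 and 0.078. Markers of macrophages, T cells and NK cells were lower there too, in 20 of 20, 16 of 20 and 12 of 14 members, with adjusted p = 0.071, 0.041 and 0.17 with an estimated correlation. The labels name no difference between the slides, and no explanation was tested.

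Genes that changed at least 2-fold over both slides, with 1 sign on each, lay close together on some chromosomes. Of the 22346 genes with a position outside the heavy chain locus 2.32% did so, against 14 of 43 (32.6%) on chromosome 1 between 175 and 180 Mb, which holds the HIN-200 and pyrin domain genes Mnda, Mndal, Ifi202b, Ifi203, Aim2, Pydc3 and Pydc4. Over both slides Aim2, a sensor of cytosolic DNA, fell by 1.33 (adjusted p 2.05e-07), while Mndal rose by 1.05 (adjusted p 1.78e-05). On chromosome 2 between 175 and 180 Mb 13 of 59 genes (22%) did, among them the zinc finger genes Etohi1 and Zfp931, and on chromosome 15 between 30 and 35 Mb 7 of 34 (20.6%), with Sema5a. On chromosome 6 between 125 and 130 Mb, which holds lectin-like receptor genes, 9 of 92 did, with Klrb1f up by 2.83 (adjusted p 1.05e-05).

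Trim12a, Trim5 and Trim34a, which lie near each other on chromosome 7, differed among deficient arrays. On slide 1 Trim34a was at 4.72, 4.13 and 3.35 in deficient arrays 9, 11 and 10 and at 0.0814 in array 12, with -0.656 to -0.243 in wild-type arrays. On slide 2 it was at 2.90 and 2.83 in deficient arrays 2 and 4 and at 0.224 and 0.72 in arrays 1 and 3. Trim5 was at 1.25, 0.32 and -0.0321 in deficient arrays 9, 11 and 10 of slide 1, at -1.50 and -1.45 in arrays 2 and 4 of slide 2, and not well above background in the others. Trim12a was well above background in those same 5 deficient arrays, and in 1 wild-type array of slide 1.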
